A study of Mus musculus with 6 samples.

How the data were processed

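RNA was measured in 6 libraries of sorted germinal centre B cells, 3 labelled WT and 3 labelled Prdm1 KO, from mixed bone marrow chimeras on day 12 after immunization. Per the labels' protocols, libraries were made with the SMART-Seq v4 kit, which reads full-length transcripts without marking strand, and Nextera FLEX, and were sequenced on NovaSeq or NextSeq instruments with an aim of 20 M paired reads of 75 bases, with some samples read at 101 bases. The labels used here do not say which samples had the longer reads, so instrument and read length could not be used as a batch. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.9a, featureCounts from Subread 2.0.1 and limma, with genome build mm10. The gene annotation and the normalization steps are not given in the sources used here.

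The deposited files give log2 values per gene, not counts. From the values themselves, 2 to the power of each library's values sums to between 995165 and 999582, so they are log2 CPM. The libraries' sorted values differed by a median of 0.017, as after quantile normalization, which makes distributions nearly equal and removes any global difference in RNA content. Of 4281 low differences, 81.0% fell within 0.002 of steps between small read numbers with 0.5 added, such as the step of 1.59 from none to 1 read. The deposited log2 values were also centred: for each of 14763 varying genes the mean of the WT and KO values with the same replicate number was equal across numbers within 0.0005, against 4.60% of genes or fewer for any other pairing. The other 8657 genes held the same value in all 6 libraries, 8613 of them at the floor of -4.84. Centring makes the SD of WT and KO identical for each gene and fixes the correlation of same-numbered samples, so the usual check of whether numbers pair the samples is void. The pairing is taken from the centring, which removes differences between numbers and leaves 2 residual degrees of freedom. The column headers of the files name the WT libraries as floxed without Cre, whereas the labels give an unmodified Prdm1 and a Cre allele. Groups were taken from the labels.

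The test fixed before the data were examined was a count model without a replicate block. Since the files used here hold log2 values, the test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on mean level, prior degrees of freedom 9.0), with the replicate number as a block and group as the coefficient. The fit without the block, which counts 4 residual degrees of freedom, became the alternative. A count model in another tool, voom weights and other size factors need counts and were not run. Genes with a mean of at least 0 log2 CPM over the 6 libraries and any variation were tested (10297 genes). No pseudocount was added to the deposited values. Calls had a Benjamini-Hochberg adjusted p under 0.05. The fit was tested on simulated data made from the real genes for KO against WT with 200 changed genes among 10297, in 9 simulations. With the block it recovered 36.2% of genes changed by 0.5 log2, 78.1% of those changed by 1 and 95.6% of those changed by 2, with 4.6% false calls. Without the block 64% of calls were false. The simulated errors were independent between genes, with variances drawn from the trend that the fit assumes. These shares therefore need not hold for the real libraries.

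Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 28 of 36 lists with at least 5 tested members. The lists cover germinal centre identity, light and dark zone, genes repressed by BLIMP1, plasma cells, the unfolded protein response, G1/S, G2/M, cyclins and CDK inhibitors, MYC targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, naive and memory B cells, apoptosis, NF-kB, MHC class II, B cell receptor signalling, immunoglobulins, migration, hypermutation, interferon, ribosomal proteins, proteasome, histones, mitochondrial and immediate early genes, other cell types and sex-linked genes. Genes are named by a rule fixed before the data were examined. It takes Prdm1, Bcl6 and Irf4, then, among called genes with a mean of at least 3 log2 CPM and all KO libraries on the same side of all WT libraries, the 10 largest rises and 10 largest falls, leaving out immunoglobulin and T cell receptor segments, predicted genes, RIKEN clones and pseudogenes. It then takes up to 4 called members of each list with the smallest adjusted p, or up to 2 with the smallest p where none passed. For centred values, separation of the libraries is the same as agreement in direction of 3 pairs: 928 of the 930 called genes and 4787 of 10297 tested genes (46.5%) were separated, against 25% by chance. Other genes named in the text were chosen after their values were seen, and a few genes the rule takes are not reported here. Those chosen afterwards are Myc, Xbp1, Sdc1, Cd38, Cd74, S1pr1, Cd55, Gpr183, Spib, Mef2b, Ccnb1, Ctsb, Cst3, Mpeg1, Cd68, the markers near the floor and the genes of hypoxia and nuclear RNA.

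Coordinates and transcript lengths come from GENCODE M21 on mm10, matched by symbol and by older symbols (526 tested genes carry a newer symbol). Of 10297 tested genes 10207 (99.1%) had a position and 90 did not. Fisher's exact test, two-sided, compared called with uncalled genes within 20 Mb of Ptprc and Prdm1, with 10 and 40 Mb as alternatives. Figures and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were no replicate block, no filter, CPM of at least 5 in at least 3 libraries, immunoglobulin genes left out, each replicate pair left out (a library without its partner carries no information under the block), an adjusted p under 0.01, and a test against a fold of 1.5. Alternatives chosen after seeing the data were no variance trend, robust variance, a pseudocount of 1 CPM on the linear scale, within-pair differences centred on their median, natural splines of 5 degrees of freedom for transcript length and GC fitted within each pair, and genes near Ptprc left out. A single library's depth is not known, and the SEs are limma's moderated values, which draw each gene's variance between pairs towards the trend (median 0.122 log2 over tested genes).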

Results

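The series profiled germinal centre B cells of mouse spleen, the B cells that proliferate and mutate their antibody genes inside follicles after immunization. The cells came from 50/50 mixed bone marrow chimeras, in which wild type and Prdm1-deficient cells develop in the same host, and were sorted on day 12 after immunization with NP-CGG in alum, a haptenated protein in adjuvant. Donors of the KO-labelled cells carried floxed Prdm1 alleles and a Cre driver, with the CD45.2 allele of the pan-leukocyte marker gene Ptprc. By the labels, donors of the WT-labelled cells carried unmodified Prdm1, the same driver and the CD45.1 allele. The column headers instead name the WT libraries as floxed without Cre, and which is right is not known. RNA was measured in 3 libraries labelled WT and 3 labelled KO, each listing log2 CPM (read counts scaled to the library's total) for 23420 genes. The depth of single libraries cannot be read from such values. If the lowest value, -4.84, stands for 0.5 read, 1 CPM was about 14.3 reads in a library of mean size. Pearson correlations between libraries, across genes, lay between 0.968 and 0.989, and no pair of libraries was identical.

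The deposited values were centred by replicate number. For each of the 14763 genes that varied, the mean of the WT and KO libraries sharing a number was equal across the 3 numbers within 0.0005. Information therefore lay in 3 within-pair differences (KO minus WT) per gene, and every comparison below was fitted on these pairs with limma, with Benjamini-Hochberg adjustment over 10297 genes. Fold changes are log2, KO minus WT, over 3 pairs, and each ± value after them is limma's moderated SE. That SE draws a gene's variance towards the trend over all genes and can differ from the spread of the gene's own pairs. With a pair left out the fit leans on that trend more. For Ctse without replicate 3 limma's adjusted p was 1.07e-192, which so few pairs cannot give by themselves. Calls gained or lost with a pair left out therefore reflect the trend as well as the gene. The sources do not say whether a replicate number stands for a separate mouse, so p-values measure the spread between these pairs, which may be partly technical.

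The question named by the series is how BLIMP1, the transcriptional repressor encoded by Prdm1, affects germinal centre B cells, and its title names cell cycle progression, BCL6 and IRF4. Prdm1 itself (chromosome 10, 44437177 to 44528501, mm10) was not lower in the libraries labelled KO. Its mean was 1.89 log2 CPM in WT and 2.58 in KO libraries, a difference of 0.69 ± 0.39 (moderated SE, n = 3 pairs, limma adjusted p = 0.293). The pair differences were 0.46, -0.44 and 2.05, so value and call depended on which pairs were kept. Without replicate 2 the difference was 1.26 (adjusted p = 0.0113), and without replicate 3 it was 0.012 (adjusted p = 0.985). A gene total can include exons outside the deleted part, so this value is only a partial check of the labels, and directions below are those of libraries labelled KO against libraries labelled WT. Bcl6 (chromosome 16, 23965052 to 23988852), the repressor that maintains the germinal centre state, stood at 7.41 in WT and 7.58 in KO libraries. The difference of 0.17 ± 0.08 was positive in 3 of 3 pairs and did not pass (adjusted p = 0.201). Without the replicate block, a fit whose errors are too small for centred values, the same difference had an adjusted p of 0.0116. Irf4 (chromosome 13, 30749226 to 30766976), which promotes plasma cell differentiation, differed by -0.10 ± 0.15 (adjusted p = 0.726), with pair differences of 0.08, -0.26 and -0.12.

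Across the transcriptome, 930 of 10297 tested genes (9.03%) passed an adjusted p of 0.05. Of these, 345 were higher and 585 lower in the libraries labelled KO, with 87 higher and 89 lower by more than 1 log2 unit. Among called genes with a mean of at least 3 log2 CPM, the largest rise was in Ak7, an adenylate kinase (chromosome 12, 105705976 to 105782447), from 2.14 to 4.30 log2 CPM, or 4.46-fold (log2 2.16 ± 0.20, adjusted p = 0.000223). Osbpl3, an oxysterol-binding protein (1.82 ± 0.26), Aif1l (1.67 ± 0.22), the sulfotransferase gene Chst1 (1.49 ± 0.19) and Fam101a (1.41 ± 0.14) followed. Rnpep, an aminopeptidase (1.39 ± 0.11), the kinase genes Matk (1.33 ± 0.32) and Cdk14 (1.28 ± 0.18), the tetraspanin gene Cd9 (1.25 ± 0.11) and Fam135a (1.25 ± 0.20) completed the 10 largest rises. The largest fall was in Ctse, encoding the aspartic protease cathepsin E (chromosome 1, 131638306 to 131675505), from 7.90 to 5.30 (-2.60 ± 0.11, adjusted p = 8.41e-07). The non-coding RNAs Malat1 (-1.82 ± 0.13), Kcnq1ot1 (-1.67 ± 0.18) and Xist (-1.31 ± 0.17) also fell. So did the chemokine receptor gene Cxcr4 (-1.76 ± 0.15), the immediate early gene Fos (-1.71 ± 0.18), the syndecan gene Sdc4 (-1.38 ± 0.21) and Fcer2a, encoding CD23 (-1.38 ± 0.18). Cd36, a scavenger receptor gene (-1.36 ± 0.26), and Satb1, encoding a chromatin organiser (-1.27 ± 0.26), completed the 10 largest falls. Each of these 20 genes moved the same way in 3 of 3 pairs, which the naming rule requires. Without replicate 3 the differences of Matk, Cd36 and Satb1 were 0.67, -0.89 and -0.83, and those of Kcnq1ot1 and Xist, which have long transcripts, were -0.95 each when adjusted for transcript length and GC. Ctse, Cxcr4 and Rnpep lie within 20 Mb of Ptprc, where 26.02% of tested genes were called. The library kit does not mark strand, so Kcnq1ot1 and Xist cannot be told apart from genes transcribed on their opposite strands. The excess of falls reversed with the replicate 3 pair left out (2914 genes, 1529 higher and 1385 lower) and without the replicate block (1751 higher and 1556 lower). With the replicate 2 pair left out 580 genes passed, and with no trend of variance on expression level 0 passed by limma (2175 at an unadjusted p under 0.05, against 2589 with the trend).

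**Figure D1:**
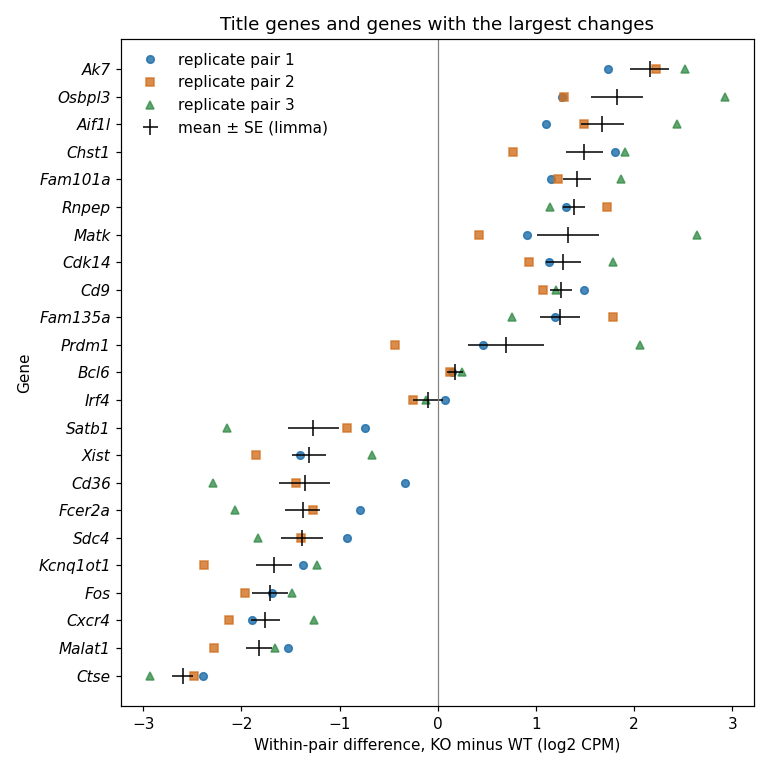
Within-pair differences (KO minus WT, log2 CPM, horizontal axis) for Prdm1, Bcl6, Irf4 and the 10 largest rises and 10 largest falls, with each of the 3 replicate pairs as a point and the limma mean ± SE as a black tick and bar. Prdm1 points run from -0.44 to 2.05 and straddle 0. The 3 points of each gene with a large change lie on the same side of 0, which the rule that chose these genes requires.

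Among 28 gene lists fixed before the data were examined and with at least 5 tested members, 16 differed from the other genes by camera at its preset correlation of 0.01, 4 upward and 12 downward. With a correlation estimated from these libraries none passed, and the lowest adjusted p was 0.656. The lowest unadjusted p of camera in that setting was 0.0730, for cholesterol synthesis. It was 0.087 for glycolysis, 0.1385 for MHC class II and 0.396 for G1/S. Adjustment gave all of these lists the same adjusted p of 0.656, so that value does not rank the lists. The estimated correlation rests on 2 residual degrees of freedom, so a list that does not pass there is not shown to be unchanged. By fry, which asks whether a list's members move one way on balance, the MHC class II list alone passed (adjusted p = 0.0341), and 21 lists passed fry's test of change in either direction. Leaving out the replicate 3 pair ended 10 of the 16 calls. Leaving out the replicate 1 pair ended 3, and leaving out the replicate 2 pair ended 2.

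**Figure D2:**
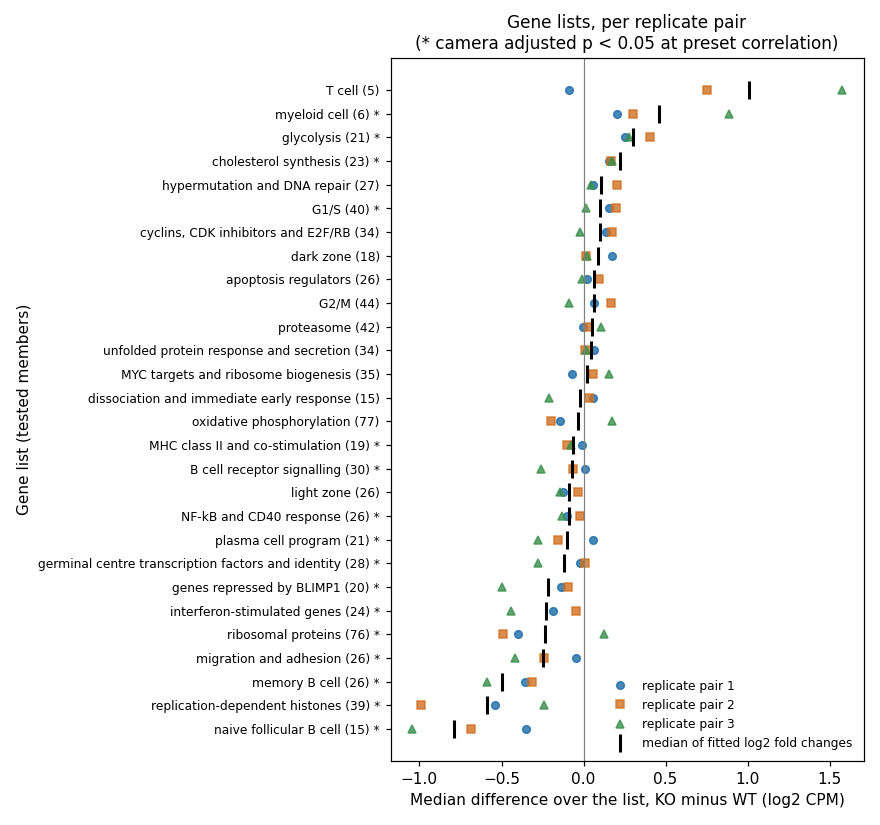
Median difference over each gene list (KO minus WT, log2 CPM, horizontal axis), with each replicate pair as a point, the median of the fitted log2 fold changes as a black tick, and the number of tested members in parentheses. Asterisks mark camera calls at the preset correlation, none of which held with an estimated correlation. The ribosomal protein medians of pairs 1 and 2 were -0.40 and -0.49 while that of pair 3 was 0.12.

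Of 21 tested genes of glycolysis, 7 rose, 0 fell and 14 did not pass (9 and 0 adjusted over the list alone). The lactate transporter gene Slc16a3 rose by 0.92 ± 0.13, the phosphofructokinase gene Pfkp by 0.48 ± 0.08, Aldoa by 0.45 ± 0.09 and Pgam1 by 0.40 ± 0.09, each in 3 of 3 pairs. The list passed camera (adjusted p = 3.88e-05), with an adjusted p of 0.656 with an estimated correlation. Of 23 genes of cholesterol synthesis, 3 rose and 20 did not pass, with 3 rising adjusted over the list alone. The list passed camera upward (adjusted p = 0.00636, and adjusted p = 0.656 with an estimated correlation). Idi1 (0.38 ± 0.09) and Sc5d (0.32 ± 0.09) were among them. Without replicate 3 the cholesterol list had an adjusted p of 0.0697. The calls of Idi1, Sc5d and Aldoa ended without replicate 1 (adjusted p = 0.162, 0.158 and 0.0559) and without replicate 2 (0.167, 0.355 and 0.0983), and that of Pgam1 without replicate 2 (0.103). The Idi1 call also ended when adjusted for transcript length and GC (0.30, adjusted p = 0.0548). None of the 77 tested genes of oxidative phosphorylation passed, by limma over all genes or adjusted over the list alone. Its lowest p belonged to Sdhd (0.26 ± 0.08, adjusted p = 0.0539) and Ndufa13 (-0.33 ± 0.10, adjusted p = 0.0758). The list had a camera adjusted p of 0.0984, and 6.94e-09 downward without replicate 3. In that setting Sdhd (adjusted p = 3.68e-05) and Ndufa13 (5.10e-17) passed, and Sdhd also passed when adjusted for transcript length and GC (0.0487).

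The cell cycle lists gave mixed values. Of 40 tested genes of the G1/S transition, 0 rose, 1 fell and 39 did not pass, with the same counts adjusted over the list alone. The list nonetheless stood above other genes by camera (median log2 0.10, adjusted p = 0.0126). Its camera adjusted p was 0.656 with an estimated correlation and 0.0761 when adjusted for transcript length and GC. It was 0.174 without replicate 1, 0.220 without replicate 2 and 1.31e-05 without replicate 3. The member that fell was Clspn, encoding the checkpoint adaptor claspin (-0.73 ± 0.12). Of 44 genes of G2 and mitosis, 1 rose, 5 fell and 38 did not pass (2 and 5 adjusted over the list alone). The proliferation marker Mki67 (-0.92 ± 0.08, adjusted p = 0.000223), the kinetochore genes Cenpe (-0.86 ± 0.09) and Cenpf (-0.80 ± 0.09) and the condensin gene Smc4 (-0.54 ± 0.08) fell in 3 of 3 pairs. Ccnb1, encoding cyclin B1, rose (0.31 ± 0.08), a call that ended without replicate 1 (0.278), without replicate 2 (0.335) and when adjusted for transcript length and GC (0.0705). The G2/M list itself was not called (camera adjusted p = 0.727), its median being 0.06 and its mean -0.01. Mki67, Cenpe and Cenpf are among the genes with the longest transcripts, of which 197 of 1021 were called lower and 20 higher in the libraries labelled KO. When adjusted for transcript length and GC, Mki67, Cenpe and Cenpf stood at -0.69, -0.72 and -0.56 and were still called. Among 34 cyclins, CDK inhibitors and E2F/RB genes, 2 rose and 1 fell, also adjusted over the list alone. Ccnd2, encoding cyclin D2, fell (-0.89 ± 0.17, and -0.57 without replicate 3), and the CDK inhibitor gene Cdkn1a (0.90 ± 0.22) and the antiproliferative gene Btg2 (0.35 ± 0.09) rose. Btg2 lies within 20 Mb of Ptprc, and its call ended without replicate 1 (adjusted p = 0.323) and without replicate 2 (0.164). The list's camera adjusted p was 0.170, and 0.0375 upward without replicate 3. Among MYC targets and ribosome biogenesis genes 1 of 35 rose, Tfrc (0.34 ± 0.08), which encodes the transferrin receptor, and 0 passed adjusted over the list alone (camera adjusted p = 0.535). The Tfrc call ended without replicate 1 (0.124) and without replicate 2 (0.189). Of 39 replication-dependent histone genes, 1 rose, 6 fell and 32 did not pass, also adjusted over the list alone. The median was -0.59 (camera adjusted p = 1.93e-05, and adjusted p = 0.656 with an estimated correlation). Hist1h1e (-0.77 ± 0.12), Hist1h2ac (-1.27 ± 0.25), Hist1h3e (-1.42 ± 0.33) and Hist1h1b (-0.69 ± 0.16) fell. Reads of these near-identical histone genes can be shared, and without replicate 2 the calls of Hist1h3e and Hist1h1b ended (adjusted p = 0.0840 and 0.154). Hist1h1b was then at -0.40 and Hist1h2ac at -0.84.

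Of 28 transcription factors and identity genes of the germinal centre, 3 rose, 8 fell and 17 did not pass (4 and 8 adjusted over the list alone). Pou2f2 (-0.63 ± 0.08), Ciita, the master regulator of MHC class II (-0.58 ± 0.08), Bach2 (-0.70 ± 0.09) and Foxp1 (-0.59 ± 0.09) fell in 3 of 3 pairs. Pou2f2, Bach2 and Foxp1 are among the genes with the longest transcripts, and stood at -0.46, -0.49 and -0.47, still called, when adjusted for transcript length and GC. S1pr2, Spib and Mef2b rose, by 0.41 ± 0.08, 0.34 ± 0.08 and 0.33 ± 0.09. The Spib and Mef2b calls ended without replicate 1 (adjusted p = 0.272 and 0.179) and without replicate 2 (0.194 and 0.291). The list passed camera downward (adjusted p = 0.0378), with an adjusted p of 0.656 with an estimated correlation and 0.985 without replicate 3. Of 20 genes reported as repressed by BLIMP1, 1 rose, 5 fell and 14 did not pass (1 and 9 adjusted over the list alone). That list had a median of -0.22 and passed camera downward (adjusted p = 0.00565, and adjusted p = 0.656 with an estimated correlation). Fcer2a, Ciita, Klf2 (-1.12 ± 0.20), a quiescence and trafficking factor, and Pax5 (-1.02 ± 0.18), the B cell commitment factor, led the falls, and Spib rose. Myc, a classical BLIMP1 target, differed by 0.20 ± 0.11 (adjusted p = 0.272), by 0.36 without replicate 1 and by 0.10 without replicate 3. The plasma cell list was called downward (camera adjusted p = 0.0345, and adjusted p = 0.656 with an estimated correlation), with 0 of 21 rising and 4 falling, also adjusted over the list alone. These were Zbtb20 (-0.66 ± 0.09), Ly6d (-0.84 ± 0.13), Cd93 (-1.87 ± 0.49) and Slpi (-0.33 ± 0.09), while Xbp1, required for secretory expansion, differed by -0.00 ± 0.08 and Sdc1 by -0.42 ± 0.44. Neither passed, and the pair differences of Sdc1 were 0.63, -0.54 and -1.34, so its sign turned (0.04) without replicate 3. Cd93, the largest of the 4 falls, had a low level, 0.98 log2 CPM in WT and -0.89 in KO libraries. The plasma cell call ended without replicate 3 (adjusted p = 0.402) and when adjusted for transcript length and GC (0.0606). That adjustment also ended the calls of Zbtb20, a gene with a long transcript (-0.21, adjusted p = 0.195), and Slpi (-0.26, adjusted p = 0.149). Without replicate 1 the S1pr2 and Slpi calls ended (0.113 and 0.186), and without replicate 2 those of S1pr2, Cd93 and Slpi (0.0752, 0.0745 and 0.0803). Igj, which encodes the joining chain and was the only measured member of the immunoglobulin lists, stood at 11.04 in WT and 11.26 in KO libraries (0.22 ± 0.09, adjusted p = 0.168, and 1.11e-05 without replicate 3). It passed adjusted over the list alone, a list with 1 tested member. Of 34 genes of the unfolded protein response and secretion 0 rose and 2 fell, also adjusted over the list alone, namely the stress factors Atf4 (-0.57 ± 0.09) and Ddit3 (-1.01 ± 0.22), and the list was not called (camera adjusted p = 0.661, median 0.04, mean -0.00).

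Of 26 light zone genes, 1 rose and 5 fell (2 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0984). The kinase gene Pim1 (-0.93 ± 0.14) and the survival genes Bcl2a1d (-0.51 ± 0.11) and Bcl2a1b (-0.40 ± 0.09) fell, and Egr2, an activation-induced factor, rose (1.17 ± 0.24, and 0.77 without replicate 3). Bcl2a1b and Bcl2a1d are near-identical copies whose reads can be exchanged, and their calls ended without replicate 1 (adjusted p = 0.0663 and 0.0654). Of 18 dark zone genes, 3 rose and 4 fell (6 and 7 adjusted over the list alone). Cxcr4, the receptor that holds cells in the dark zone, Mki67 and the ubiquitin ligase gene Fbxw7 (-0.71 ± 0.11) fell, and Polh, a polymerase of hypermutation, rose (0.52 ± 0.11). The dark zone list was not called (camera adjusted p = 0.731), its median being 0.09 and its mean -0.11. Among 27 hypermutation and repair genes, Polh rose and Rif1 fell (-0.41 ± 0.09), with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.197). Without replicate 1 the Polh call ended (0.0616), and without replicate 2 those of Polh, Rif1 and Bcl2a1b (0.0954, 0.158 and 0.149). Rif1 also lost its call when adjusted for transcript length and GC (-0.25, adjusted p = 0.0734).

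Of 15 tested markers of naive follicular B cells, 2 rose, 8 fell and 5 did not pass (2 and 11 adjusted over the list alone), with a median of -0.79 and pair medians of -0.35, -0.69 and -1.05. Fcer2a, Klf2, Bank1, an adaptor of the B cell receptor (-0.79 ± 0.14), and Foxp1 were among the falls. Cd38 (0.47 ± 0.09) and Faim3 (0.50 ± 0.08), both abundant in naive B cells, rose, and Faim3 lies within 20 Mb of Ptprc. The Cd38 call ended without replicate 1 (adjusted p = 0.0801) and without replicate 2 (0.0534). The naive list kept a camera adjusted p under 0.05 with each pair left out (adjusted p = 0.000182 with all pairs, and adjusted p = 0.656 with an estimated correlation). The memory B cell list, which shares members such as Cd38, Klf2, Gpr183, Fcer2a, S1pr1 and Cd55 with the naive list, had 26 tested genes, of which 4 rose, 8 fell and 14 did not pass (4 and 15 adjusted over the list alone). Bcl2, encoding the survival factor, fell from 2.71 to 0.39 (-2.32 ± 0.29, adjusted p = 0.00109). Tbx21, encoding T-bet (0.88 ± 0.12), and Nt5e, encoding CD73 (0.85 ± 0.12), rose. The memory list was called downward, with a camera adjusted p of 0.00704, and had an adjusted p of 0.656 with an estimated correlation and 0.0619 without replicate 3. Of 26 migration and adhesion genes, 3 rose and 5 fell (3 and 9 adjusted over the list alone). Cd9 and S1pr2, a receptor that confines cells to the follicle, rose, and Cxcr4 and Klf2 fell (camera adjusted p = 0.0177, adjusted p = 0.656 with an estimated correlation and 0.631 without replicate 3). Of 26 apoptosis regulators, 3 rose and 4 fell (5 and 4 adjusted over the list alone). The caspase gene Casp6 (0.88 ± 0.13) was among the rises, and Bcl2 and the pro-apoptotic Bak1 (-0.78 ± 0.16) fell. The list was not called (camera adjusted p = 0.661). Without replicate 2 the Bak1 and S1pr2 calls ended (0.0830 and 0.0752), and without replicate 1 that of S1pr2 (0.113).

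Of 30 genes of B cell receptor signalling, 2 rose, 5 fell and 23 did not pass (2 and 7 adjusted over the list alone). The inhibitory receptor gene Siglecg fell (-0.71 ± 0.10), and Nfatc1 (0.55 ± 0.08) and Bcl10 (0.32 ± 0.08) rose. The list was called downward (camera adjusted p = 0.0345), with an adjusted p of 0.793 with an estimated correlation and 0.729 without replicate 3. Of 26 NF-kB and CD40 response genes 0 rose and 3 fell, the inhibitor gene Nfkbia (-0.37 ± 0.10), Bcl2a1b and Bcl2a1d, with 0 and 4 adjusted over the list alone. That list had a camera adjusted p of 0.0345, with an adjusted p of 0.656 with an estimated correlation, 0.174 without replicate 1, 0.220 without replicate 3 and 0.0574 when adjusted for transcript length and GC. Of 19 genes of MHC class II and co-stimulation 0 rose and 2 fell, Ciita and Ifi30 (-0.41 ± 0.08), a thiol reductase of antigen processing, with 0 and 4 adjusted over the list alone. Its median was -0.07 (camera adjusted p = 0.0476, and adjusted p = 0.656 with an estimated correlation), and the call ended without any of the replicates 1, 2 and 3 (0.138, 0.138 and 0.0658). Cd74, the invariant chain gene, was listed at 14.0 log2 CPM in all 6 libraries and could not be tested. Of 24 interferon-stimulated genes 0 rose and 4 fell (0 and 5 adjusted over the list alone), with Ifi27l2a (-0.66 ± 0.10), Stat2 (-0.44 ± 0.12), Ifi203 (-1.44 ± 0.31) and Oas1a (-1.12 ± 0.29), the latter a pair from families with similar copies. The list had a camera adjusted p of 0.00636, with an adjusted p of 0.656 with an estimated correlation and 0.181 without replicate 3. Without replicate 1 the calls of Bcl10, Nfkbia, Ifi30, Bcl2a1b and Bcl2a1d ended (0.152, 0.343, 0.0726, 0.0663 and 0.0654), and without replicate 2 those of Bcl10, Nfkbia, Ifi30, Bcl2a1b and Stat2 (0.184, 0.204, 0.0814, 0.149 and 0.0958).

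The ribosomal protein list had medians of -0.40 and -0.49 in pairs 1 and 2 and of 0.12 in pair 3. Of 76 tested genes, 0 rose, 9 fell and 67 did not pass (0 and 18 adjusted over the list alone). Rps12 (-0.65 ± 0.16), Rpl28 (-0.53 ± 0.12), Rps15 (-0.52 ± 0.13) and Rpsa (-0.47 ± 0.12) were among them. Many processed copies of these genes can share their reads. The list's camera adjusted p was 5.59e-11, with an adjusted p of 0.656 with an estimated correlation. The calls of Rpl28, Rps15 and Rpsa ended without replicate 1 (0.0716, 0.0827 and 0.262), and those of Rps12, Rpl28, Rps15 and Rpsa without replicate 2 (0.0613, 0.108, 0.128 and 0.261), with Rps12 then at -0.43. When adjusted for transcript length and GC, Rps15 stood at -0.25 and was not called (adjusted p = 0.0608). None of 42 proteasome genes passed, over all genes or adjusted over the list alone. Psmd14 (0.23 ± 0.08, adjusted p = 0.0906) and Psmd2 (0.19 ± 0.08, adjusted p = 0.174) had the lowest p and passed without replicate 3 (0.000603 and 5.79e-06), and the camera adjusted p was 0.295.

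Markers of other cell types were mostly near the floor. The T cell genes Cd3e and Cd4 averaged -3.67 and -3.12 log2 CPM and the myeloid genes Csf1r and Itgam -2.81 and -3.93. The myeloid list also held genes well above the floor. Ctsb averaged 7.70, Cst3 7.20, Mpeg1 4.27 and Cd68 3.21, and these did not pass over all genes. Of 5 tested genes of the T cell list 2 rose (2 and 2 adjusted over the list alone), the kinase gene Lck (1.01 ± 0.14), at 7.61 in WT and 8.62 in KO libraries, and the checkpoint receptor gene Pdcd1 (2.34 ± 0.50), from -0.40 to 1.94 and by 1.53 without replicate 3. The T cell list was not called (camera adjusted p = 0.341), and had an adjusted p of 0.0203 without replicate 1 and 0.0185 without replicate 2. Of 6 tested genes of the myeloid list 2 rose (3 and 0 adjusted over the list alone), Apoe (0.59 ± 0.15), an apolipoprotein at 9.07 in WT and 9.66 in KO libraries and higher by 0.29 without replicate 3, and the haem oxygenase gene Hmox1 (1.22 ± 0.21). That list was called upward (camera adjusted p = 0.0345), with an adjusted p of 0.656 with an estimated correlation and 0.175 without replicate 3. Of 15 dissociation and immediate early genes, Fos and Jun (-1.07 ± 0.14) fell and Btg2 rose, with 2 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.678). The remaining lists had fewer than 5 tested members and no list test. Over all genes as adjusted over the list alone, Car2 rose in the erythroid list (0.62 ± 0.17, 1 tested gene), Il2rb in the natural killer list (1.06 ± 0.27, 1 tested gene) and neither of the platelet genes Itgb3 (0.17 ± 0.14) and Nrgn (0.44 ± 0.42) passed. Without replicate 3 Itgb3 passed at 0.37 (adjusted p = 0.00986) and Nrgn stood at -0.41 (0.238). Vim fell in the follicular dendritic and stromal list (-0.58 ± 0.11, 1 of 2 tested genes), and Xist in the sex-linked list (1 tested gene). Car2 lost its call without replicate 2 (0.0855) and without replicate 3 (0.0551). Immunoglobulin variable and mitochondrially encoded genes were not analysed here, since 0 of either list were measured.

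By the labels, WT and KO donors differed in the CD45 allele as well as in Prdm1, so called genes were counted around both loci. If the column headers are right, Cre differed between the groups as well. Within 20 Mb of Ptprc (chromosome 1, 138062861 to 138175708), 32 of 123 tested genes were called (26.02%), 17 higher and 15 lower, against 882 of 10084 elsewhere (8.75%). The odds ratio was 3.67 (95% interval 2.36 to 5.58, Fisher's exact test, two-sided, p = 2.05e-08, adjusted p = 1.23e-07 over 6 tests of 2 loci and 3 windows). It was 1.94 without replicate 3 and 2.12 without the replicate block, past the threshold in both. Within 40 Mb of Ptprc, 45 of 235 tested genes were called (19.15%), against 869 of 9972 elsewhere (8.71%). The odds ratio there was 2.48 (95% interval 1.74 to 3.48), and the 45 genes included Bcl2 and Ifi203. Within 20 Mb of Prdm1, 10 of 111 tested genes were called (9.01%), an odds ratio of 1.01 (95% interval 0.467 to 1.94, Fisher's exact p = 1.0, adjusted p = 1.0). Genes on a chromosome are not independent, so these p-values can be too low. Calls also varied with transcript length. The tenth of genes with the longest transcripts comprised 1021 whose longest annotated transcript reached 6665 bases or more. In it 197 were lower and 20 higher, and the median difference was -0.15, with pair medians of -0.11, -0.14 and -0.24.

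**Figure D3:**
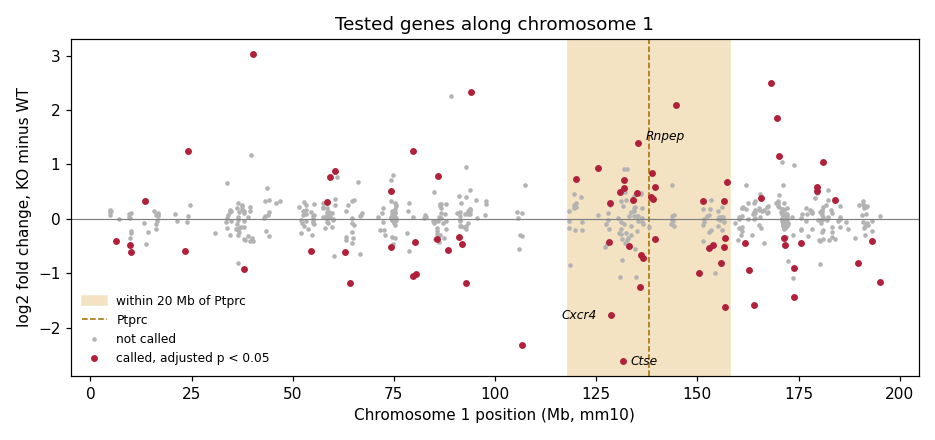
Log2 fold change (KO minus WT, vertical axis) of tested genes by position along chromosome 1 (Mb, mm10), with genes called at an adjusted p under 0.05 in red, other genes in grey, Ptprc as a dashed line and the 20 Mb on either side shaded. In the shaded window 32 of 123 genes were called, among them Ctse and Cxcr4 with large falls and Rnpep with a large rise.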

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

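The settings without a variance trend, with robust variance, with a pseudocount, centred on the median, adjusted for length and GC and without genes near Ptprc were chosen after the data were seen. Main counts were 930 called genes, 345 higher and 585 lower. Without the replicate block, whose pairing the centring of the values imposes, 3307 genes were called (1751 higher, 1556 lower), and 927 of the main calls were among them. That fit's errors are too small for centred values, and Bcl6 at 0.17 passed in it. Leaving out a replicate pair gave 580 to 2914 genes, 226 to 1529 higher and 354 to 1385 lower. The low is without replicate 2, the high without replicate 3, and 498 and 923 main calls were shared with them. The p-values of the fits with a pair left out lean strongly on the variance trend of the kept pairs. Higher calls outnumbered lower ones in those without replicate 3 and without the block. An adjusted p under 0.01 gave 310 (85 and 225), and a tested fold of 1.5 gave 18 (8 and 10), both stricter by construction. Without a variance trend 0 genes, 0 higher and 0 lower, passed in limma, with 2175 at an unadjusted p under 0.05; the cause was not tested. The other settings gave 881 to 1083 genes. Prdm1 was 0.012 to 1.26 with a pair left out and passed at 1.26, without replicate 2. Irf4 kept its sign and did not pass in any setting. Gene lists called were 16, and 8 to 15 with a pair left out, 10 without a variance trend, 0 with an estimated correlation and 1 by fry, which tests another question. The estimated correlation rests on 2 residual degrees of freedom, and the cause of the drop to 0 was not tested. The odds ratio near Ptprc stayed above 1 and past the threshold in every setting that gave a value, from 1.94 without replicate 3 to 24.2 at a fold of 1.5. Near Prdm1 it was 1.01 and never passed. It lay below 1 at 0.960 with the stricter filter, 0.805 to 0.966 with a pair left out, 0 at a fold of 1.5, 0.997 when centred on the median and 0.725 within 10 Mb; the cause was not tested. Of 90 called genes picked by rule (title genes, largest changes and list members), 17, 25 and 1 lost their call without replicates 1, 2 and 3 and 5 when adjusted for length and GC, and none changed direction. A count model in another tool, voom weights and other size factors were not run. Read depth per library is not known, so differences in genes near the floor were not detectable below a limit that cannot be stated.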

Other observations

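The tests of explanations and of the hypoxia and nuclear RNA lists, and the genome windows, were chosen after the main results were seen, whereas the main count of calls and the count around Ptprc were planned. Beyond the fixed lists, 15 genes of the hypoxia response outside glycolysis were tested, and 5 were higher and 0 lower in the libraries labelled KO. Bnip3, a mitophagy receptor (0.86 ± 0.09, adjusted p = 0.000567), Bnip3l (0.44 ± 0.09), the collagen prolyl hydroxylase gene P4ha1 (0.68 ± 0.14), Ndrg1 (1.09 ± 0.26) and Hif1a (0.46 ± 0.08) rose in 3 of 3 pairs, and without replicate 1 the calls of P4ha1 and Hif1a ended (0.0621 and 0.0580). The list was written after Bnip3 and P4ha1 had been noticed. Without them, camera on the remaining 13 genes gave p = 0.00169 upward, and p = 0.183 with an estimated correlation. At the preset correlation only, this met the prediction that hypoxia response genes beyond those noticed stand higher. The whole list was written after the main results were seen, so the remaining genes are not an independent test. Both p-values are unadjusted.

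The real grouping called 930 genes with the replicate block. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone gave as many genes (1 of 10), and the highest count among the others was 0 by limma, with at most 736 at an unadjusted p under 0.05 against 2589. That includes the splits that part all 3 pairs, as the real one does, and they differ from it by exchanging the labels within a pair. Among these at most 483 genes had an unadjusted p under 0.05. The count of 736 came from a split that parts 1 pair, which alone informs it under the block. In every other split the KO minus WT difference adds to the error. The 0 calls there therefore cannot settle whether 930 could arise without a genotype effect.

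Called genes crowded around Ptprc. The tables argue against transcript length and GC content as the source, since the odds ratio was 2.76 (95% interval 1.75 to 4.25) with both removed within pairs. The odds ratio of 3.67 (2.36 to 5.58) is the crowding itself and so does not test donor DNA linked to the CD45 allele, which may account for it and stays open. No other window of the same width with at least 50 tested genes, of 236 away from Ptprc, had as large a share of calls, but chromosome 15 up to 40000000 came close, with 17 of 67 genes (25.4%) against 26.02%. An effect of Prdm1 on the 32 called genes in the window, Ctse and Cxcr4 included, cannot be told apart from linked DNA, because all libraries of a genotype share a CD45 allele.

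Genes with the longest transcripts were more often lower (197 lower, 20 higher among 1021; odds ratio of a lower call 5.62, 95% interval 4.63 to 6.79). With length and GC removed within pairs, 110 of the 197 were still called lower, which argues against this trend as the whole cause. For the other 87 the median went from -0.53 ± 0.18 (SD) to -0.28 ± 0.16 while the median SE went from 0.112 to 0.105, so their calls ended because the fold shrank, and a length trend stays open for them. A lower content of nuclear RNA could contribute: apart from Malat1, Xist and Kcnq1ot1, which were noticed first, the 3 tested nuclear-retained RNAs Neat1, Ftx and Jpx had a median of -0.26, at the 19.0 percentile of 10000 random lists matched on level, too few genes to decide. An effect of the Prdm1 genotype was not tested and stays open.

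Of 15 tested naive B cell markers, 8 were called lower, 2 higher and 5 neither, with the lowest median in pair 3. The list's camera call did not hold with an estimated correlation (adjusted p = 0.656). The tables argue against the length and GC trend, since 8 of the 8 markers called lower were still called lower with it removed. A smaller number of naive B cells carried through the sort of the KO-labelled cells may explain part of the change: the median of the markers was -0.79 with an SD of 0.66. Against it, Cd38 at 6.01 and Faim3 at 8.83 log2 CPM in KO libraries were higher by 0.47 and 0.50 (the Cd38 call ended without replicate 1 and without replicate 2, at 0.0801 and 0.0534). Germinal centre cells also express several of these markers, Faim3 lies near Ptprc, and the labels do not give the sorting gate, so this and an effect of the Prdm1 genotype stay open.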
